A study of Homo sapiens with 6 samples.

How the data were processed

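Gene expression was measured in SUM149 cells, a human cell line of inflammatory breast cancer, after transient transfection with an siRNA pool, at 200 nmol/L per the labels' protocols. Of the 6 arrays, 3 came from cells given a non-targeting control pool (siControl) and 3 from cells given a pool against TIG1 (siTIG1), the gene whose current symbol is RARRES1. Per the labels' protocols, the control pool was of the siGENOME product line and the TIG1 pool of the ON-TARGET Plus line, so the 2 groups differed in both the target and the kind of siRNA. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

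The deposited table holds 1 log2 value per probe set and array for Affymetrix HG-U133 Plus arrays, hybridised with biotin-labelled cRNA per the labels' protocols. The log base is not written in the table. It was taken as 2 because the values run from 4.28 to 15.59, the span of a scanner's intensity on that scale. MAS5 and RMA are both named in the submitters' processing notes, with no role or version. Which of them made the deposited log2 values is not given in the sources used here. Array medians lay between 7.87 and 7.90, and the sorted values of the 6 arrays differed by at most 0.093, so the authors' log2 values were already normalized between arrays and were used as deposited. Normalization of this kind fixes each array's distribution, so a shift of most genes one way could not be seen. Summarised log2 values carry no detection call and no background estimate, so low values have no stated floor. A low signal is therefore not shown to lie above background, and a fold measured against it can be too small.

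The 54675 probe sets include 62 control probe sets, which stayed out of all gene tests. Of the other 54613, 41091 were paired with 1 gene symbol in the platform annotation, 1801 with several and 11721 with no symbol listed. Symbols were updated through the gene number against the RefSeq table of assembly GRCh38.p14, which held 19735 of the 19775 genes. No coordinates are given, since no build is named for the array's annotation. Each gene was represented by 1 probe set, the one with the highest mean over the 6 arrays, and probe sets whose name ends in x_at, which can bind several transcripts, were taken only where a gene had no other. Probe sets of close paralogs such as SERPINB3 and SERPINB4 can share signal.

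The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, without a block), with Benjamini-Hochberg adjustment over the 19775 genes and a threshold of 0.05. Differences are log2 siTIG1 minus siControl with the standard error of the moderated fit, and means carry the SD over 3 arrays. All adjusted p-values below come from limma. The number of arrays limits the precision. On data simulated for this comparison with the measured means and spreads of the 19775 genes and 200 changed genes, the test recovered 56.7% of changes of 0.5 on the log2 scale, 86.6% of changes of 1 and 97.0% of changes of 2, with 11 false calls. The simulated noise was independent between genes. These figures therefore do not cover a shift of many genes together on 1 array, as seen below for siControl replicate 3.

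Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, apart from those said to be later. The 28 lists covered the TAM receptors, NF-kB targets, interferon response, metalloproteinases, epithelial, mesenchymal, basal and luminal genes, S phase, G2 and M phase, p53 targets, apoptosis, the unfolded protein and integrated stress response, heat shock, cholesterol and fatty acid synthesis, hypoxia and glycolysis, MAPK feedback, TGF-beta, retinoids, stem cell markers, the small RNA pathway, double-stranded RNA sensing, oxidative phosphorylation, ribosomal proteins, and markers of leukocytes, fibroblasts and endothelial cells. Each was tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Some list members had no probe set with 1 symbol and were not analysed here.

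Named genes were RARRES1, AXL and GAS6, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher mean lay above the median gene level of 8.69, up to 4 members by p of each list that was called or had at least 3 members past the threshold, and up to 2 of each other list by size of difference. Genes outside the rule that complete a count, and MMP9, DUSP6 and MERTK, were chosen after their values were seen. Alternatives were quantile normalization, median centring, a filter on dim genes, the mean of a gene's probe sets, all probe sets, a trended robust prior, array weights, the replicate number as a block, fold and p thresholds, and each array left out. Lists of FOXO targets, complement and acute-phase genes, and metallothioneins were added after the data were seen, as were camera with an estimated correlation and 1 array left out, and TIG1 losses against all 3 controls. Other pseudocounts did not apply to values already on a log scale.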

Results

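The series compared SUM149 cells transfected with siRNA against TIG1 with cells transfected with a non-targeting control pool, 3 arrays per group, to find which transcripts differ after TIG1 knockdown. Each array gave 54675 probe set values, from which 19775 genes were tested. Within the siTIG1 group the arrays correlated at 0.998 to 0.999 across probe sets, and siControl replicates 1 and 2 correlated at 0.998. The array of siControl replicate 3 stood apart from both other controls, with correlations of 0.985 and 0.985, and lay farther from them than the siTIG1 arrays did, which correlated with siControl replicates 1 and 2 at 0.992 to 0.993.

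TIG1 (RARRES1, retinoic acid receptor responder 1) was measured by 3 probe sets, and its mean signal was lower in the siTIG1 group on each of them, but none passed the test. They are called probe sets 1, 2 and 3 in the order of their identifiers. Probe set 1 averaged 11.52 ± 0.93 (SD, n = 3) on the control arrays and 10.24 ± 0.42 (SD, n = 3) on the siTIG1 arrays, a log2 difference of -1.28 ± 0.46 (SE, limma adjusted p = 0.20 over all probe sets). Probe set 2 differed by -1.24 ± 0.48 (SE, limma adjusted p = 0.23), and probe set 3, which represents the gene in the gene-level fit, by -0.83 ± 0.36 (SE, limma adjusted p = 0.25). Exact 2-sided permutation tests gave p = 0.1, 0.1 and 0.3 for the 3 probe sets, where 0.1 is the smallest that 3 against 3 arrays allow.

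Single arrays stood apart within both groups for TIG1. The control array of replicate 3 read 1.60 above the mean of the other controls on probe set 1, 1.66 above on probe set 2 and 1.11 above on probe set 3. The array labelled siTIG1 replicate 1 read 0.06 above the mean of siControl replicates 1 and 2 on probe set 3, and its differences from them were -0.27 and -0.17 on the other probe sets. The arrays of siTIG1 replicates 2 and 3 together differed from the same controls by -0.98, -0.94 and -0.72. Without siControl replicate 3 the difference was -0.75 on probe set 1 (limma adjusted p = 0.024), -0.68 on probe set 2 (limma adjusted p = 0.043) and -0.46 on probe set 3 (limma adjusted p = 0.16 over all probe sets). The groups below follow the labels, and directions drawn from the siTIG1 group include this array.

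**Figure D1:**
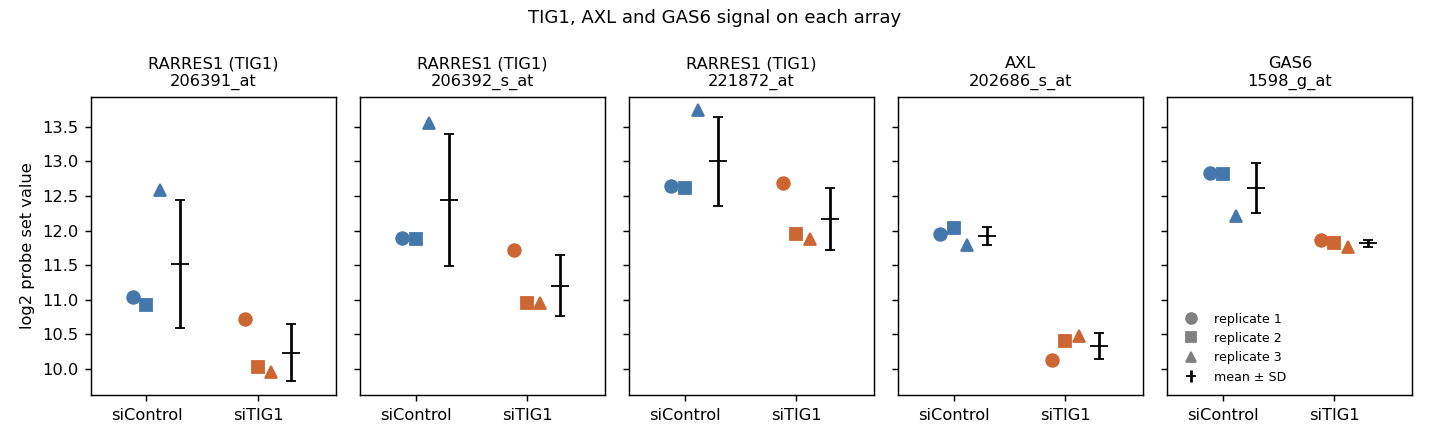
Log2 probe set values (y axis) of the 3 TIG1 probe sets, AXL and GAS6 on each array (symbols give the replicate), with group means ± SD (black bars, n = 3). TIG1 values of siControl replicate 3 lie above the other controls and those of siTIG1 replicate 1 lie near siControl replicates 1 and 2, whereas all 3 siTIG1 arrays lie below all 3 control arrays for AXL and GAS6.

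AXL, a receptor tyrosine kinase of the TAM family, and GAS6, the secreted ligand of these receptors, both fell in the siTIG1 group. AXL averaged 11.92 ± 0.13 (SD, n = 3) on the control arrays and 10.33 ± 0.18 (SD, n = 3) on the siTIG1 arrays, 3.01-fold lower, with a log2 difference of -1.59 ± 0.11 (SE, limma adjusted p = 0.0024). Both AXL probe sets had this sign, and 1 of the 2 passed. GAS6 was 1.75-fold lower, at -0.80 ± 0.17 (SE, limma adjusted p = 0.045). PROS1, which encodes protein S, another ligand of the family, rose by 0.33 ± 0.06 (SE) from a low level of 6.62 (limma adjusted p = 0.025). Of the 8 measured TAM receptor and ligand genes 1 rose, 2 fell and 5 did not pass, and adjusted over the list alone the counts were the same 1 and 2. TYRO3 was at -0.11 and MERTK at -0.06 on the log2 scale. The list as a whole was not called by camera (adjusted p = 0.26), but was as lower by fry (adjusted p = 0.034). The AXL call was kept with any 1 array left out (limma adjusted p of at most 0.029), whereas leaving out any array other than siControl replicate 3 ended those of GAS6 (0.12 to 0.18) and PROS1 (0.083 to 0.12).

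Across the genome, 624 genes were higher and 818 lower in the siTIG1 group at an adjusted p under 0.05 by limma, 1442 of 19775. Most differences were small: the median size was 0.49 on the log2 scale, and 98 higher and 52 lower genes differed by at least 2-fold. In 31.8% of all genes tested all 3 arrays of a group lay above all 3 of the other, which chance gives for 10% of genes. The count depended on every array. It was 5357 without siControl replicate 3, 588 without siControl replicate 1, 521 without siControl replicate 2, 442 without siTIG1 replicate 1, 217 without siTIG1 replicate 2 and 264 without siTIG1 replicate 3. All 1442 genes also passed, with the same sign, without siControl replicate 3.

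The largest measured rise was that of FBXO32, the muscle ubiquitin ligase subunit atrogin-1, from 9.84 ± 0.08 to 13.15 ± 0.07 (SD, n = 3 each), a 9.91-fold difference (log2 3.31 ± 0.07 SE, limma adjusted p = 3.7e-05) seen with the same sign on all 7 of its probe sets. GBP1, an interferon-inducible GTPase, rose from a low control signal of 5.90 ± 0.61 to 9.14 ± 0.16 (SD, n = 3 each), measured as 9.46-fold. The squamous cell carcinoma antigens SERPINB4 and SERPINB3, near-identical paralogs whose probe sets can share signal, rose 9.29-fold and 6.59-fold. NPY1R, a neuropeptide Y receptor, rose 7.87-fold, the matrix metalloproteinase MMP7 6.97-fold and the immediate-early transcription factor EGR1 6.90-fold. The other leading rises were OLFML3 (4.99-fold), the estrogen sulfotransferase SULT1E1 (4.67-fold), complement factor I (CFI, 4.55-fold), the matrix proteoglycan decorin (DCN, 4.49-fold) and the non-coding RNA NRAD1 (4.38-fold). The control signal of GBP1 is not shown to lie above background, nor are those of NRAD1, CFI, NPY1R, DCN, SERPINB4 and SULT1E1 (means of 7.19 to 7.97), so the sizes of these rises and their order are uncertain. Among these 12 genes the adjusted p of limma was highest for MMP7, at 0.020. With 1 array left out, the calls of MMP7 and SERPINB3 were lost for at least 1 choice of array (highest adjusted p of 0.098 and 0.059).

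The largest measured fall was that of SHISA2, which was 5.21-fold lower (log2 -2.38 ± 0.25 SE, limma adjusted p = 0.0059). FOSL1, a subunit of the AP-1 transcription factor, was 3.97-fold lower, and SLC7A11, the cystine transporter, 3.96-fold lower. The transmembrane collagen COL13A1 was 3.76-fold lower, but 1 of its 3 probe sets had the opposite sign. The calpain CAPN8 was 3.73-fold lower and PHLDA1 3.10-fold lower, followed by AXL. Genes of the extracellular matrix among these falls were LAMB3, a chain of the basement membrane protein laminin-332, 2.88-fold lower, and COL6A3, a chain of collagen VI, 2.71-fold lower. PROSER1 was 2.81-fold lower, uridine phosphorylase UPP1 2.77-fold lower and the EGF receptor ligand epiregulin (EREG) 2.72-fold lower. The siTIG1 signals of SHISA2, COL13A1 and CAPN8 (means of 6.86, 7.11 and 7.62) are likewise not shown to lie above background. Sizes and order also depend on siControl replicate 3. Without it the log2 differences of FOSL1, CAPN8, PHLDA1, PROSER1 and UPP1 shrank to -1.64, -1.53, -1.27, -1.15 and -1.11. Those of SHISA2, COL13A1 and AXL grew to -2.69, -2.02 and -1.66. The highest adjusted p of limma among these 12 genes was 0.037, for UPP1. Of the 24 genes with the largest rises and falls, 14 kept their call with any 1 array left out, and the falls that did not were SHISA2, FOSL1, SLC7A11, CAPN8, PHLDA1, PROSER1, UPP1 and EREG.

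**Figure D2:**
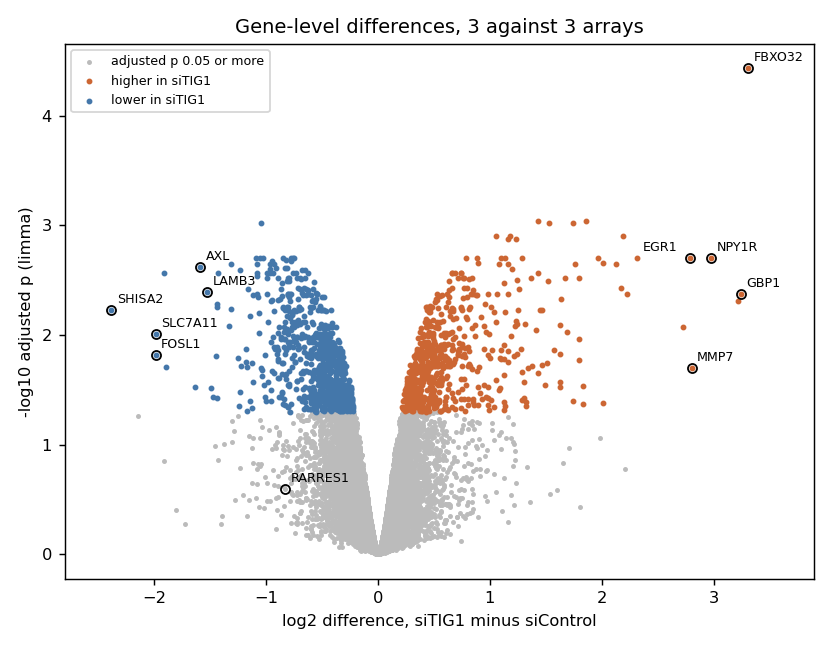
Log2 difference of each of 19775 genes, siTIG1 minus siControl (x axis), against -log10 of its limma adjusted p (y axis). Of the genes past 0.05, 624 are higher (orange) and 818 lower (blue) in siTIG1, and RARRES1 itself lies below the threshold.

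Of 24 measured genes of MAPK feedback and growth factor response 11 fell, 3 rose and 10 did not pass, and the list was called as lower (median log2 difference -0.69, camera adjusted p = 7.9e-06). The call was lost with an estimated correlation (adjusted p = 0.62) and with fry (adjusted p = 0.096). Adjusted over the list alone, 16 fell and 3 rose. The falls included FOSL1, PHLDA1 and EREG, the EGF receptor ligand TGFA (-0.80 ± 0.07 SE, limma adjusted p = 0.0043) and the ETS factor ETV4 (-0.83 ± 0.09 SE, limma adjusted p = 0.0059). The rises were EGR1 (2.79 ± 0.17 SE), FOS (1.76 ± 0.12 SE) and JUN (0.85 ± 0.17 SE, limma adjusted p = 0.038), which encode immediate-early transcription factors. EGR1 and FOS had the smallest limma p of the list and went against its median. The fall of FOSL1 (-1.99 on the log2 scale) was larger in size than the rise of FOS. The phosphatase gene DUSP6 differed by -1.92 ± 0.62 (SE, limma adjusted p = 0.14), with siControl replicate 3 far above the other controls. It read 12.77 on that array, 10.51 and 10.45 on the other controls and 9.08 to 9.63 on the siTIG1 arrays. Without that array 18 members fell and 3 rose, with a median of -0.67, and without any other single array 1 to 6 fell and 2 rose.

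Of 37 measured interferon response genes 12 rose, none fell and 25 did not pass, and the list was called as higher, with 33 positive differences and a median of 0.31 on the log2 scale (camera adjusted p = 4.3e-09). The call was kept under fry (adjusted p = 0.034) and lost with an estimated correlation (adjusted p = 0.62). Adjusted over the list alone 20 rose. IFI44L rose by 1.41 ± 0.17 (SE, limma adjusted p = 0.0090), IFI27 by 0.84 ± 0.10 (SE, limma adjusted p = 0.0087), the helicase-like gene DDX60 by 0.79 ± 0.07 (SE, limma adjusted p = 0.0045) and IFIH1, the double-stranded RNA sensor MDA5, by 0.59 ± 0.08 (SE, limma adjusted p = 0.013). Of 13 measured genes of double-stranded RNA sensing, IFIH1, TLR3 (1.33 ± 0.28 SE) and IRF3 (0.40 ± 0.09 SE) rose and 10 did not pass, and that list was not called (camera adjusted p = 0.12). With the siControl replicate 3 array left out, 19 interferon genes rose and none fell, and 4 double-stranded RNA sensing genes rose and 1 fell. Without any other single array 2 to 6 interferon genes and at most 1 sensing gene rose. The difference between the 3' and 5' control probe sets of ACTB, which grows as RNA degrades, was 2.85 ± 0.31 on the control arrays and 2.25 ± 0.10 on the siTIG1 arrays (SD, n = 3 each, exact permutation p = 0.1, 2-sided). The same measure for GAPDH was 0.50 ± 0.06 and 0.46 ± 0.01 (exact permutation p = 0.2), a difference of -0.04 with the same sign, and siControl replicate 3 had the highest value of both measures.

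The list of NF-kB target genes was called as higher, close to the threshold (median 0.10, camera adjusted p = 0.048), and the call was lost with an estimated correlation (adjusted p = 0.84). On the siControl replicate 3 array the list's median lay 0.27 above the other controls. Its deviation from the 6-array mean there, 0.065, was within the range of the siTIG1 arrays (0.056 to 0.088). Of 26 measured members TNFAIP3, the inhibitor A20 (1.24 ± 0.14 SE, limma adjusted p = 0.0080), the chemokine CXCL1 (0.96 ± 0.19 SE), mitochondrial superoxide dismutase SOD2 (0.63 ± 0.12 SE) and the adhesion molecule ICAM1 (0.48 ± 0.10 SE) rose, none fell and 22 did not pass (6 rose when adjusted over the list alone). The call was lost without siControl replicate 1 (adjusted p = 0.14), siControl replicate 2 (0.15) or siTIG1 replicate 3 (0.069). Without siControl replicate 3, 13 members rose and 2 fell (median 0.20, camera adjusted p = 0.00025, but adjusted p = 0.37 with an estimated correlation), and without any other single array at most 1 rose.

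Among matrix metalloproteinase and invasion genes 3 rose, 2 fell and 18 did not pass, and the list was not called (camera adjusted p = 0.54), except as higher at the preset correlation over every probe set (0.017). In the gene-level fit with an estimated correlation it had a camera adjusted p = 0.82. Adjusted over the list alone 4 rose and 2 fell. The rises were MMP7, MMP2 (gelatinase A, 0.54 ± 0.11 SE) and cathepsin B (CTSB, 0.28 ± 0.06 SE), and the falls were the sheddase ADAM8 (-1.02 ± 0.06 SE, limma adjusted p = 0.0020) and cathepsin D (CTSD, -0.51 ± 0.07 SE). Of 2 ADAM8 probe sets 1 had the opposite sign. MMP9, gelatinase B, averaged 8.92 ± 0.23 on the control arrays and 8.60 ± 0.13 on the siTIG1 arrays (SD, n = 3 each), a difference of -0.32 ± 0.13 (SE) that did not pass (limma adjusted p = 0.22). Without siControl replicate 3 the MMP9 difference was -0.45 and passed (limma adjusted p = 0.0018), and 9 members of the list rose and 4 fell. Without any other single array at most 1 rose and 1 to 2 fell.

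Retinoid response and metabolism genes were called as higher (median 0.14, camera adjusted p = 0.016), a call lost with an estimated correlation (adjusted p = 0.82). Of 21 measured members 7 rose, 2 fell and 12 did not pass, and 9 rose and 3 fell when adjusted over the list alone. The retinol dehydrogenase RDH10 (1.24 ± 0.14 SE), the nuclear receptor corepressor NRIP1 (1.18 ± 0.15 SE) and RAI14 (0.69 ± 0.09 SE) rose, whereas the retinol acyltransferase LRAT (-1.07 ± 0.10 SE) and the retinaldehyde dehydrogenase ALDH1A3 (-0.66 ± 0.09 SE) fell. The call was lost without siControl replicate 2 (adjusted p = 0.052). Without siControl replicate 3, 10 members rose and 3 fell, and without any other single array at most 3 rose and 1 to 2 fell.

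The unfolded protein and integrated stress response list was called as lower (median -0.30, camera adjusted p = 0.0068), but 22 of its 25 measured members did not pass. The call was lost with an estimated correlation (adjusted p = 0.82) and with fry (adjusted p = 0.53). Those that fell were SLC7A11, the ER degradation factor EDEM1 (-0.51 ± 0.07 SE) and the serine synthesis enzyme PSAT1 (-0.33 ± 0.07 SE), and 5 fell when adjusted over the list alone. The list's median on the siControl replicate 3 array was 0.77 above the other controls, and without that array the median difference was -0.01, 4 members rose, 8 fell and the call was lost (camera adjusted p = 0.28). Without any other single array at most 2 fell.

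The result for cell cycle genes depended on the control arrays. None of 30 S phase or 32 G2 and M phase genes passed limma's threshold in the comparison of all arrays, also when adjusted over the list alone, and 0 did at an unadjusted p under 0.05. The list medians were 0.09 and 0.12. On the control array of replicate 3 these lists lay 1.25 and 0.75 below the other controls. Without it 26 S phase genes and 13 G2 and M phase genes fell and none rose, with medians of -0.29 and -0.15 (camera adjusted p = 7.9e-13 and 0.00041 at the preset correlation). Members of each list moved together (estimated correlations of 0.99 and 0.95 with all arrays), and neither list was called with an estimated correlation (adjusted p = 0.95 for both with all arrays, 0.091 and 0.62 without that array). Without siControl replicate 2 the G2 and M phase list was instead called as higher (camera adjusted p = 0.014), but not with an estimated correlation (adjusted p = 0.89). Cyclin E2 (CCNE2), with the S phase list's highest difference, was at 0.74 ± 1.08 (SE) with all arrays and at -0.61 without that array.

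**Figure D3:**
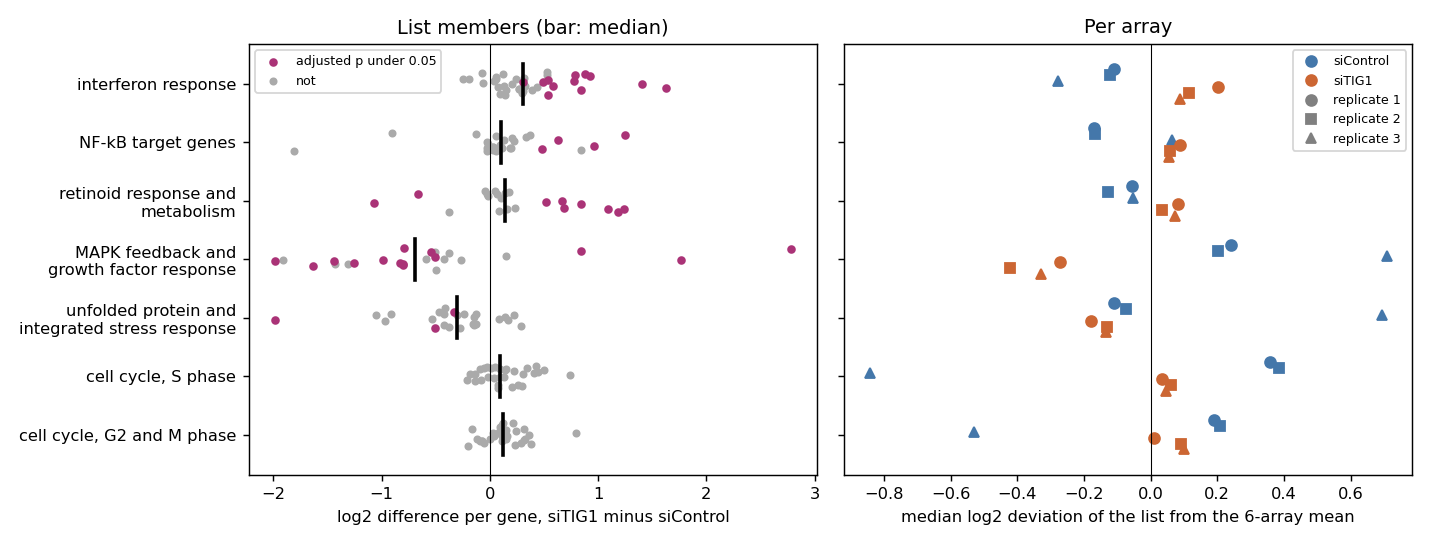
Left, log2 difference of each member of 7 gene lists, siTIG1 minus siControl (x axis), with the list median as a bar and members past the threshold in purple. Right, the median deviation of each list on each array from the 6-array mean (log2). The siControl replicate 3 array lies farthest from the other controls for the cell cycle, stress response and MAPK lists. For the NF-kB list it lies among the siTIG1 arrays.

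Genes that mark cell state changed in both directions. Among mesenchymal genes the transcription factors SNAI1 (1.26 ± 0.11 SE) and TWIST1 (0.81 ± 0.12 SE) and the fibrillin FBN1 (0.77 ± 0.16 SE) rose and COL6A3 fell, while 20 of 24 did not pass (5 rose and 2 fell when adjusted over the list alone). Of 25 epithelial junction genes P-cadherin (CDH3, 0.49 ± 0.05 SE) rose and MAL2 (-0.37 ± 0.07 SE) fell, also when adjusted over the list alone. Among basal and squamous genes KRT15 (0.75 ± 0.10 SE), S100A8 (0.80 ± 0.07 SE) and S100A9 (0.43 ± 0.06 SE) rose and the laminin-332 pair LAMB3 and ITGA6 (integrin alpha 6, -1.05 ± 0.07 SE) fell, the same 3 and 2 when adjusted over the list alone. Of 21 luminal genes keratin 19 (KRT19, 1.00 ± 0.15 SE) rose and the carbonic anhydrase CA12 (-0.90 ± 0.07 SE) fell, with 2 and 1 when adjusted over the list alone. Among 16 stem cell markers 4 rose and 2 fell, also when adjusted over the list alone. CD24 was up by 1.47 ± 0.23 (SE) on all 6 of its probe sets. It marks breast cancer stem cells by a low level, not a high one, so these counts give no direction for that state. WNT5A (0.51 ± 0.07 SE), ALDH1A1 (0.51 ± 0.11 SE) and HES1 (0.62 ± 0.14 SE) were up as well. The falls were CD44 (-0.84 ± 0.11 SE) and ALDH1A3. Of the 13 probe sets of CD44, 11 had that sign and 1 passed. None of these 5 lists was called (camera adjusted p = 0.29, 0.88, 0.91, 0.85 and 0.80), but the mesenchymal list was called as higher at the preset correlation over the mean of each gene's probe sets (0.046) and over every probe set (0.00021). In the gene-level fit with an estimated correlation that list had a camera adjusted p = 0.82. With siControl replicate 3 left out, 10 mesenchymal genes rose and 2 fell, against 8 and 4 epithelial, 6 and 6 basal, 5 and 3 luminal and 6 and 2 stem cell genes. Without any other single array at most 2 rose and at most 2 fell in each list.

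Among metabolic and stress genes, the hypoxia and glycolysis list had 2 rises, aldolase C (ALDOC, 0.76 ± 0.06 SE) and the collagen prolyl hydroxylase P4HA2 (0.76 ± 0.06 SE, 2 of 3 probe sets with this sign), and 3 falls, the enolase ENO2 (-1.02 ± 0.19 SE), the glucose transporter SLC2A1 (-0.60 ± 0.11 SE) and hexokinase HK2 (-0.56 ± 0.12 SE), of 28 (4 and 4 when adjusted over the list alone). In the heat shock list HSPB1 (1.22 ± 0.18 SE), DNAJB4 (1.13 ± 0.25 SE) and the collagen chaperone SERPINH1 (0.60 ± 0.12 SE) rose, 14 did not pass, and the same 3 rose when adjusted over the list alone. Of 21 TGF-beta response genes CCN2 (1.10 ± 0.16 SE) rose, and SMAD3 (-0.69 ± 0.12 SE, 3 of 4 probe sets with this sign) and LTBP2 (-0.42 ± 0.07 SE) fell, against 5 rises and 2 falls when adjusted over the list alone. Of 22 p53 targets TP53I3 (0.75 ± 0.08 SE) rose and AEN (-0.54 ± 0.07 SE) fell (4 and 2 over the list alone). Of 18 apoptosis regulators BIRC2 (0.33 ± 0.07 SE) rose, and BCL2L1 (-0.60 ± 0.12 SE) and BID (-0.36 ± 0.06 SE) fell, the same 1 and 2 when adjusted over the list alone. None of these 5 lists was called with all arrays (camera adjusted p = 0.80, 0.068, 0.25, 0.91 and 0.91). The heat shock list (median 0.24) was called as higher at the preset correlation without siControl replicate 1 (camera adjusted p = 0.020), siControl replicate 2 (0.014) or siTIG1 replicate 1 (0.011), but not with an estimated correlation (adjusted p = 0.79, 0.79 and 0.83). On the siControl replicate 3 array that list was at -0.40 relative to the other controls, and without this array its median was 0.04 (camera adjusted p = 0.47). When siControl replicate 3 was left out, 6 hypoxia and glycolysis genes rose and 9 fell, against 3 and 1 heat shock genes, 8 and 6 TGF-beta genes, 7 and 4 p53 targets and 5 and 2 apoptosis regulators. Without any other single array at most 2 rose and at most 1 fell in each list.

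In the remaining lists at most 2 members passed. Adjusted over the list alone the counts were the same, apart from 2 falls in the small RNA pathway. LSS fell among 19 cholesterol synthesis genes, LPIN1 among 14 fatty acid synthesis genes and RPL22 among 22 ribosomal protein genes. SDHC rose and CYC1 fell among 27 genes of oxidative phosphorylation. DROSHA rose and PRKRA, which encodes the protein activator PACT, fell by 0.72 ± 0.08 (SE) on the log2 scale among 14 genes of the small RNA pathway. Camera adjusted p-values for these 5 lists were 0.87, 0.26, 0.25, 0.10 and 0.71. Leaving out siControl replicate 3 gave 2 rises and 6 falls among cholesterol synthesis genes, 2 and 5 in fatty acid synthesis, 1 and 1 in ribosomal proteins, 4 and 2 in oxidative phosphorylation and 3 and 5 in the small RNA pathway, and leaving out any other array gave at most 1 of each. Of the marker lists of other cell types, DCN rose among 13 fibroblast genes while the fibroblast activation protein gene FAP was at 0.92 ± 0.26 (SE, limma adjusted p = 0.101), and none of 13 leukocyte or 10 endothelial markers passed by limma (2 and 1 at an unadjusted p under 0.05). Without the siControl replicate 3 array 2 fibroblast genes and 1 leukocyte gene rose and 1 endothelial gene fell. With all arrays the camera adjusted p-values of these lists were 0.43, 0.88 and 0.87. No list was called with an estimated correlation, where the smallest adjusted p was 0.62, or 0.091 with 1 array left out. The camera adjusted p also grew for lists whose estimated correlation lay below the preset. It went from 0.12 to 0.62 for double-stranded RNA sensing (-0.018) and from 0.10 to 0.62 for oxidative phosphorylation (-0.022). With an estimated correlation camera is limited by the small number of arrays. A call lost under this test is therefore not put down to correlated members alone, and does not show that the list did not move.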

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

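The tests on the replicate arrays, on RNA quality and on the siRNA pools were chosen after the results were seen, and the tests of chance splits and of the interferon list without 1 array at the preset correlation were planned.

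Signals outside the gene comparison also separated the groups. The 18 probe sets of bacterial RNAs added as hybridisation controls averaged 11.73 ± 0.02 on the control arrays and 11.92 ± 0.06 on the siTIG1 arrays (SD, n = 3 each), a log2 difference of 0.20 with all 3 siTIG1 arrays above all 3 controls (exact permutation p = 0.1, the smallest possible). The ACTB 3' to 5' difference also separated all 3 siTIG1 arrays from all 3 controls. Bacterial RNAs are not made by the cells, so a difference in sample handling may coincide with the groups. It may contribute to any of the gene and list differences above and cannot be told apart from the siRNA. Of 13522 probe sets without 1 gene symbol, 355 passed limma's threshold, 131 higher and 224 lower in siTIG1.

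The siControl replicate 3 array differed from both other controls by at least 4-fold in many genes, 32 above and 25 below, whereas siControl replicates 1 and 2 differed by at least 2-fold in 0 genes. The cytokine genes IL24 and IL1A were 31.6-fold and 15.3-fold above the mean of the other controls, and CCNE2 was 16.5-fold below. An exchange of labels with a siTIG1 array is argued against, since its highest correlation with a siTIG1 array (0.982) was below those with the other controls and no siTIG1 array lay with the controls. The ACTB 3' to 5' difference was 3.21 on this array against 2.73 and 2.62. Lower RNA quality as the whole cause was taken to leave few genes at least 4-fold above both controls, and 32 lay there. That criterion was set after the array was seen. No array of known degraded RNA was available for comparison, so the count does not settle the matter. Leukocyte, fibroblast and endothelial markers had median shifts of at most 0.0748. A different state of that culture, or a sample from elsewhere, stays open and was not tested.

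Against siControl replicates 1 and 2, the array labelled siTIG1 replicate 1 had TIG1 losses of 0.27, 0.18 and -0.08 of those on replicates 2 and 3, on TIG1 probe sets 1, 2 and 3, and against all 3 controls of 0.53, 0.49 and 0.29. Over 500 genes chosen on the other siTIG1 arrays, with separate control arrays on both sides, its changes were 0.94 of theirs. Of these genes 497 had the same sign. The 95% bootstrap interval of 0.91 to 0.96 resampled genes on fixed arrays, so it holds no spread between arrays. The TIG1 shares carry no interval. Changes in proportion to the loss of TIG1 signal on each array are argued against for these arrays, since all 6 shares, at most 0.53, lie far below 0.94. An exchange with a control is also argued against, since the array's lowest correlation with the other siTIG1 arrays (0.998) was above those with every control. Other transcripts hit by the siRNA pool may contribute and cannot be told apart from effects of TIG1, because the files hold 0 siRNA sequences and 1 pool was used. A difference between TIG1 transcript and protein on that array also stays open, untested.

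The interferon response list was called as higher in siTIG1 at camera's preset correlation but not with an estimated correlation (adjusted p = 0.62 with all arrays, 0.48 without siControl replicate 3). That array as the whole cause is argued against, since without it 19 members rose, none fell and the preset correlation gave a camera adjusted p = 9.5e-08, with a median of 0.24. RNA quality may contribute: the shift per unit of ACTB difference seen within the control arrays, which rests on siControl replicate 3, would give 0.16 of the observed 0.31. The 2 siRNA pools may be sensed differently by the cell, and the double-stranded RNA sensing list was not called (camera adjusted p = 0.12). Pool, target and group coincide, so these cannot be told apart.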

How the results depend on the processing

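All alternatives here were planned, apart from an estimated correlation with 1 array left out. The count of 1442 changed genes (624 higher, 818 lower) changed with most settings. It was 2737 probe sets when every probe set was tested (1171 and 1566), 5109 with array weights (2392 and 2717), 525 at 1.5-fold or more (246 and 279), 150 at 2-fold or more (98 and 52) and 324 at an adjusted p under 0.01 (151 and 173). With the replicate block it was 245 (108 and 137), but the arrays share only a number: deviations of same-numbered arrays from their group means correlated at -0.08, 0.02 and -0.04. Leaving out 1 array gave 217 to 5357 genes (101 to 2421 higher, 116 to 2936 lower). Other normalizations, the filter on dim genes, mean probe sets and the trended robust prior kept the counts within 1.5 times. The TIG1 difference at gene level did not pass under any alternative, with -0.46 to -1.09 when 1 array was left out. On TIG1 probe set 1 it passed with array weights (-0.90) and without siControl replicate 3 and spanned -0.75 to -1.58 with 1 array left out. On probe set 2 it passed without siControl replicate 3 and spanned -0.68 to -1.52. Of the 5 lists called by camera, 0 were called with an estimated correlation (adjusted p of 0.62 for interferon and MAPK, 0.82 for retinoid and stress response, 0.84 for NF-kB) and 2 of all 28 lists by fry, the interferon and TAM lists (fry 0.096 for MAPK, 0.11 for retinoid, 0.53 for stress response, 0.52 for NF-kB). The NF-kB call was lost among genes above the median level (0.11). The stress response call was lost among those genes (0.051), over every probe set (0.059) and with array weights (0.12). With 1 array left out the adjusted p spanned 0.00025 to 0.15 for NF-kB, 0.000794 to 0.28 for the stress response and 0.0030 to 0.052 for retinoid genes. The heat shock list, not called with all arrays (0.068), was called as higher with quantile normalization (0.047), median centring (0.046) and among genes above the median level (0.038), and spanned 0.011 to 0.47 with 1 array left out. These are values at the preset correlation, and with an estimated correlation and all arrays the list was at 0.84. The S phase list turned lower with array weights (adjusted p = 1.5e-05) and without siControl replicate 3 (7.9e-13, against up to 0.89 without another array), as did the G2 and M phase list without it (0.00041, up to 0.72; with an estimated correlation 0.091 and 0.62) and the CCNE2 difference (-0.61, up to 1.43). The cause was not tested. No other named gene changed sign with a call before or after (MCM6 went from 0.50 to -0.19 without siControl replicate 3 and passed in neither). The replicate block ended 41 calls of named genes, and 26 of 78 named genes past the threshold kept their call with any 1 array left out. Of 10 splits of the 6 arrays, 1, the real one, gave 1442 genes by limma, and the highest other gave 0 (at most 1034 at an unadjusted p under 0.05, against 4323), but 10 splits are too few for a share under 0.05.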

Other observations

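The lists of FOXO targets, complement and acute-phase genes and metallothioneins were chosen after the largest changes had been seen, and the genes that prompted the FOXO and complement lists were left out of their tests.

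Because FBXO32, a known target of FOXO transcription factors, had the largest measured rise, other FOXO targets were tested as a hypothesis. Of 25 measured targets 4 rose (SOD2 by 0.63, CCNG2 by 0.48, CDKN1B by 0.37 and TNFSF10 by 0.35 on the log2 scale), IRS2 fell by 0.82 and 20 did not pass, with a median difference of 0.18. The list was higher with limma's camera (adjusted p = 0.00515 over the 3 lists, 0.00172 before adjustment), and also without siControl replicate 3 (4.8e-06 before adjustment). It was not called with an estimated correlation (0.19 before adjustment). Higher FOXO activity may therefore accompany the rise of FBXO32, but transcript levels do not measure it, and SOD2 is also in the NF-kB list.

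CFI rose together with C1S (log2 difference 1.75) and SERPINA3 (2.01), which encode complement and acute-phase proteins. Of 24 other genes of that kind C1R rose by 0.72 and clusterin (CLU) by 0.45, none fell, and the list was not called with limma's camera (adjusted p = 0.265 over the 3 lists, 0.176 before adjustment, median 0.04). Without siControl replicate 3 camera gave 0.0121 before adjustment, with a median of 0.07. On the same arrays C3 was at 0.41, CFB at 0.38 and LCN2 at -0.36. A list not higher at a camera p under 0.05, with a median of 0.1 or less, had been set as evidence against a rise of the whole group. Both parts held with all arrays, but without siControl replicate 3 only the median met the rule. A rise of the whole group is therefore left undecided. Members went both ways, and several, such as CRP at 7.11 and FGG at 6.78, had low signal on the control arrays. Beyond CFI, C1S, SERPINA3, C1R and CLU, a rise of further members stays open.

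Among metallothionein genes, MT1X and MT2A were at -2.64 and -2.36 on the siControl replicate 3 array against the other controls, whereas MT1G was at 0.13 and MT3 at -0.04. The 6 genes that lay far below (MT1E, MT1F, MT1H, MT1HL1, MT1X and MT2A) are represented by probe sets that can bind several transcripts and share signal, so they are not 6 separate observations. The tested list of 11 genes also holds the regulator MTF1 and the zinc transporter SLC30A1. Between the groups its median difference was 0.42 with all arrays (limma camera adjusted p = 0.275) and -0.15 without that array (0.0572 before adjustment).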
